A study of Mus musculus with 12 samples.

How the data were processed

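Small RNA libraries from the CA1 subfield of 6 Control and 6 Kat2a cKO mice were analysed from 3 count tables. Per the labels' protocols, total RNA was extracted with TRI Reagent, treated with DNase and purified again, and libraries were made with Illumina small RNA kits and cut from a gel. Per the submitters' processing notes, base calling used CASAVA, with no version stated. The aligner, the annotation release and the genome build are not stated, so no coordinates are given. Per the file headers and their whole-number values, each table deposited by the authors holds raw read counts with no normalization.

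The miRNA table has 495 named miRNAs; 1 row without a name (0.00015% of reads) was left out. Every miRNA in it has a Control mean of 10 or more counts, while the lowest cKO mean is 7.33, so the rows look chosen on the Control mean, and miRNAs below that mean in Control are not analysed here. Such a choice could tilt rows near that mean towards lower levels in cKO. The permutation tests and splits take the rows as given, and the size of such a tilt was not tested. The misc RNA table has 4645 rows in classes of tRNA, ncRNA and other misc RNA; 302 rows with over 200 reads, 234 of them tRNAs, form 84 sets of identical rows. The table of all RNAs has 35230 RefSeq transcript rows, of which 26081 were matched to gene symbols by accession in a RefSeq table of assembly GRCm38.p6, and 9149, with 4.35% of reads, were not. There 3097 genes have several rows, and for some overlapping transcripts, such as Rtl1 and Mir127, the row with most reads differs between libraries; how reads that match several transcripts were counted is not stated. Its columns carry run numbers that match no sample title, so they were assigned to groups only; the order of the groups and, within a group, of the totals is that of the miRNA table, and was not used to match them.

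Counts of each table were analysed by edgeR 4.0.16 in R 4.3.3: rows kept by filterByExpr, TMM factors, a quasi-likelihood fit on group, a two-sided test and Benjamini-Hochberg adjustment over the rows tested, with a threshold of 0.05. Calls in the table of all RNAs were counted as transcript rows. Rows of miRNA, snoRNA, small nuclear, guide and Y RNA genes and of names in the misc RNA table stayed in the fit. They were left out of that count. CPM values are TMM-scaled. Gene lists were tested by camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, for lists with 3 or more tested members; fry and camera with an estimated correlation were alternatives. Shares of counts and library scores were compared by exact two-sided permutation tests over 924 assignments. Intervals and SEs come from the fit with 6 libraries per group and hold for counting and biological spread together. PCR reads carry no molecular identifiers here.

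The design, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took, per table, the 10 tested features with the smallest p (since fewer than 10 passed), the 5 most abundant, 4 members of each list that passed, the 2 most abundant members of each list of another cell type, Kat2a and Kat2b; 1 feature the rule takes is not used here. The lists were neuron-enriched, activity-linked, Dlk1-Dio3, let-7, miR-17, miR-34, miR-183, miR-29, miR-30, miR-181, oligodendrocyte, microglia, vascular, erythroid, choroid plexus and Hox miRNAs; classes of misc RNA; and immediate early, NF-kB, excitatory neuron, dentate and CA3, interneuron, oligodendrocyte, astrocyte, microglia, vascular, choroid plexus, haemoglobin, mitochondrial, ribosomal protein, snoRNA host and SAGA genes. The miR-183, Hox, Y RNA, 7SL and 7SK lists had under 3 tested members, the mitochondrial and ribosomal RNA classes had none in the misc RNA table, and the gene lists not given in the report had under 3 tested rows.

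Alternatives were RLE size factors, DESeq2 1.42.0, no filter, 10 counts in 6 libraries, voom with quality weights, a robust fit, the replicate number as a block, and each library left out. Added after seeing the data were replicate numbers 1 to 3 against 4 to 6 as a covariate, each of those sets alone, 1 surrogate variable (sva 3.50.0), the total of the miRNA and misc RNA tables, identical rows kept once, rows of a gene summed, and Rtl1 counted with the miRNAs. Hairpin GC and neighbouring miRNA genes came from GENCODE M21.

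The fit was tested on simulated counts drawn from the real means, library sizes and dispersions. In the miRNA table (489 tested, 98 changed, since the table is small) 51.5%, 72.7% and 93.8% of miRNAs changed 1.5-fold, 2-fold and 4-fold were recovered. In the misc RNA table (1053 tested, 200 changed) the shares were 13.4%, 49.3% and 95.5%. In the table of all RNAs (1637 tested, 200 changed) they were 1.49%, 2.99% and 39.4%. False calls were 1 of 72, 11 of 116 and 3 of 32. With the 74 Dlk1-Dio3 members shifted in simulated miRNA counts by log2 values of 0, -0.15 and -0.3, the fitted median was 0.00, -0.08 and -0.27. Camera then called 0, 1 and 2 lists, of which 0, 0 and 1 were false. Each miRNA was drawn independently, in a single draw per shift. The simulated members thus carry no correlation, and the draws cannot show how often camera calls a list falsely when members are correlated.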

Results

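Small RNA was sequenced from the dissected CA1 subfield of the hippocampus of adult C57BL/6J mice aged 3 to 5 months. Control mice carried floxed Kat2a alleles without Cre (n = 6). Kat2a cKO mice carried the same alleles with a CamKIIα-driven Cre recombinase, which acts in forebrain excitatory neurons (n = 6). Kat2a is a histone acetyltransferase of the SAGA and ATAC complexes. Each library was counted in a table of miRNAs, a table of other small non-coding RNAs (misc RNAs) and a table of all RNAs. Total counts per library were 2449121 to 10116062 in the miRNA table, 1779081 to 8586979 in the misc RNA table and 1119938 to 4464600 in the table of all RNAs. The difference in miRNA totals between groups was within the spread of libraries (n = 6 each, exact two-sided permutation p = 0.50). Column names in the table of all RNAs give a group but no single mouse, so its libraries carry letters in column order.

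The targeted gene came first, as a check of the labels. Kat2a had 23 reads over the 6 Control libraries and 13 over the 6 cKO libraries, with 0 to 8 reads per library. Its mean level was 2.23 ± 2.44 CPM (normalised read counts) in Control and 0.95 ± 0.97 CPM in cKO (SD, n = 6 each, exact two-sided permutation p = 0.28). Of the 23 Control reads 8 came from library b, without which the difference of -1.28 CPM became -0.32 CPM. Kat2b, its closest paralog, had 7 and 15 reads, with means of 0.58 ± 0.51 and 0.93 ± 0.92 CPM (SD, n = 6 each, exact permutation p = 0.42). Both lay under the count filter of the gene fit. In a fit with no filter the smallest adjusted p of the 2 Kat2a transcript rows was 0.73 (edgeR). In a small RNA library these reads are fragments of any exon, deleted or not, so a loss of Kat2a was not detectable at this depth.

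The first comparison asked which miRNAs differ between Control and Kat2a cKO CA1. The miRNAs of the imprinted Dlk1-Dio3 locus, a large maternally expressed cluster with many members active in neurons, fell together in cKO. Of its 74 tested members, 60 had a lower fitted level and 14 a higher one, with a median log2 difference of -0.12 (camera, adjusted p = 3.2e-06). The mean log2 level of the locus differed by -0.13, against SDs between libraries of 0.03 in Control and 0.02 in cKO. It was below the Control mean in 6 of 6 cKO libraries (n = 6 each, exact two-sided permutation p = 0.0022, the smallest that these groups can give). Among single miRNAs, miR-203, an epithelial miRNA, rose from 63.3 ± 8.29 to 105 ± 11.02 CPM (SD, n = 6 each), a log2 fold change of 0.73 ± 0.13 (SE).

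The fall of the Dlk1-Dio3 group was small for each member. With an estimated correlation between members the list had an adjusted p = 0.00077. It stood in replicate numbers 1 to 3 (difference of means -0.14) and in numbers 4 to 6 (-0.11), 2 sets of libraries that differed in miRNA profile. None of the 74 members passed the test over all miRNAs, and 0 passed adjusted over the list alone. The 4 members with the smallest p were miR-376b, miR-337-5p, miR-376a and miR-379. Their log2 fold changes were -0.33 ± 0.13, -0.44 ± 0.22, -0.57 ± 0.29 and -0.31 ± 0.16 (SE). Each was below the Control mean in 6 of 6 cKO libraries. The 2 most abundant members, miR-127 and miR-434-3p, had log2 fold changes of -0.06 ± 0.15 and -0.04 ± 0.22.

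**Figure D1:**
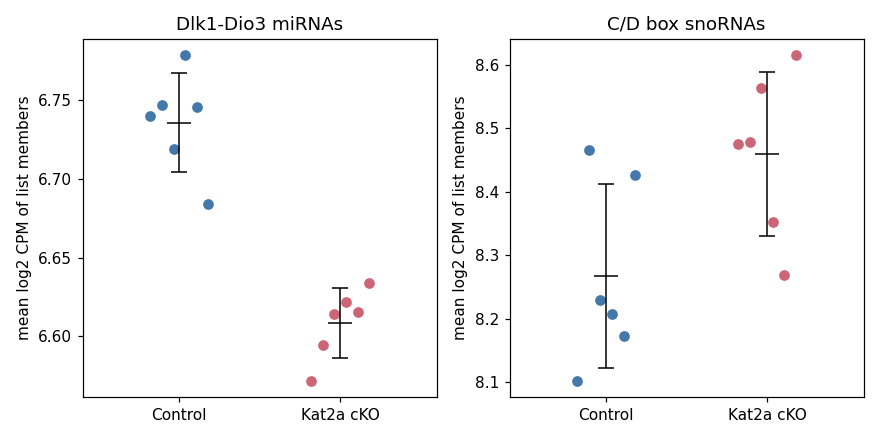
Mean log2 CPM of the tested members of the Dlk1-Dio3 miRNA list (left) and of the C/D box snoRNA list (right) in each library, by group; points are libraries, black bars the mean and SD (n = 6 each), and the vertical axes do not start at 0. For the Dlk1-Dio3 miRNAs the 6 cKO libraries lie below the 6 Control libraries, with a difference of means of -0.13; for the C/D box snoRNAs the difference is 0.19 and the groups overlap.

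Of the tested miRNAs, 1 passed an adjusted p of 0.05 (edgeR), miR-203 with an adjusted p = 0.039; 21 had an unadjusted p under 0.05. DESeq2 called 2 miRNAs, with miR-221 lower (log2 fold change -0.32, adjusted p = 0.013) beside miR-203 higher. In edgeR miR-221 went from 2114 ± 189 to 1700.3 ± 102 CPM, a log2 fold change of -0.31 ± 0.11 (adjusted p = 0.997). The miR-203 call ended without any 1 of the 12 libraries, where its log2 fold change was 0.67 to 0.76 and its adjusted p 0.061 to 0.16. The call also ended when libraries were scaled by the total of the miRNA and misc RNA tables (log2 fold change 0.68, adjusted p = 0.66), in numbers 1 to 3 alone (0.93, adjusted p = 0.998) and in numbers 4 to 6 alone (0.54, adjusted p = 0.24). It was lost too with the replicate number as a block.

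The next miRNAs by p did not pass the edgeR test, with adjusted p values of 0.997. Higher fitted levels in cKO were seen for miR-199a-5p (log2 fold change 0.69 ± 0.21), miR-491* (0.88 ± 0.28), miR-152* (0.61 ± 0.21), miR-187 (0.50 ± 0.18), miR-1947 (0.43 ± 0.16), miR-31* (0.53 ± 0.20) and the erythroid miR-451 (0.44 ± 0.17). The abundant brain miRNAs miR-181a, miR-26a and miR-22 had log2 fold changes of 0.00 ± 0.11, -0.12 ± 0.10 and -0.09 ± 0.12.

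**Figure D2:**
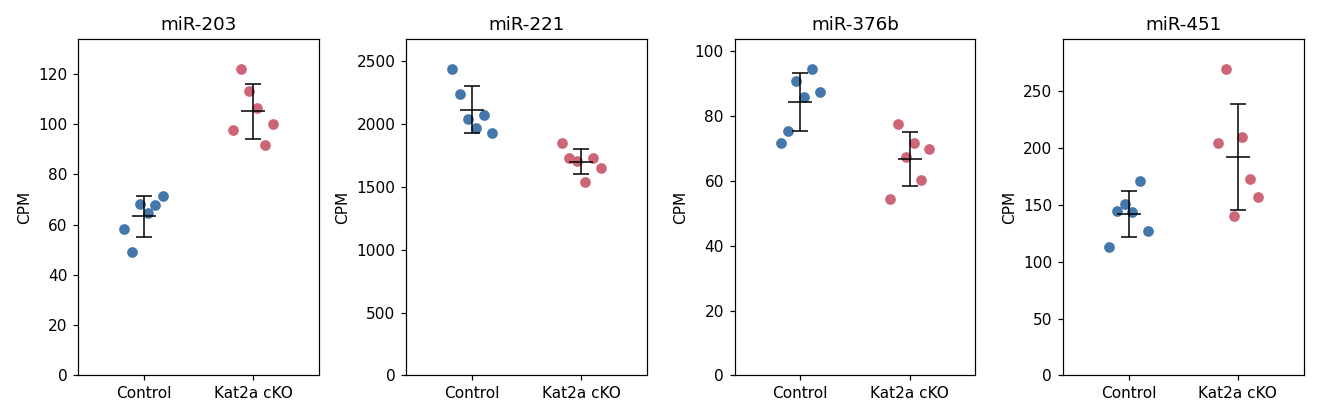
Levels of miR-203, miR-221, miR-376b and miR-451 in CPM in each library, by group, with axes from 0; points are libraries and black bars the mean and SD (n = 6 each). The 6 cKO libraries lie above the 6 Control libraries for miR-203, with means of 105 and 63.3 CPM; the other 3 miRNAs did not pass the edgeR test.

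No other miRNA list passed. The neuron-enriched miRNAs, such as miR-9 and miR-128, had a median log2 difference of -0.02 over 22 members, 16 lower and 6 higher (adjusted p = 0.75). The activity-linked miRNAs, such as miR-132 and miR-134, had a median of -0.02 over 15 members (adjusted p = 0.69). The let-7 family had a median of -0.02 (21 members, adjusted p = 0.94), the miR-17 clusters 0.01 (17, 0.75), miR-29 -0.12 (7, 0.52), miR-30 0.05 (11, 0.70), miR-34 and miR-449 -0.27 (6, 0.52) and miR-181 0.06 (6, 0.69).

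Lists of other cell types did not pass the test in the miRNA table. The oligodendrocyte miRNAs had a median of -0.23 over 5 members (adjusted p = 0.20); miR-338-3p and miR-219-3p had log2 fold changes of -0.24 ± 0.19 and -0.27 ± 0.16. The red blood cell miRNAs had a median of 0.32 over 4 members (adjusted p = 0.097); miR-486 and miR-451 had 0.16 ± 0.38 and 0.44 ± 0.17. Without Control 2, cKO 3 or cKO 6 that list passed, with adjusted p values of 0.018, 0.039 and 0.043. The vascular miRNAs had a median of 0.14 over 6 members (adjusted p = 0.52), with miR-126-5p at 0.11 ± 0.18 and miR-143 at 0.17 ± 0.19. The microglia and leukocyte miRNAs had a median of -0.04 over 8 members (adjusted p = 0.75), with miR-21 at 0.00 ± 0.24 and miR-146b at 0.08 ± 0.17. The choroid plexus and epithelial miRNAs had a median of 0.03 but a mean of -0.18 over 9 members (adjusted p = 0.62), with miR-204 at 0.13 ± 0.29 and miR-429 at -0.29 ± 0.47. The Hox cluster miRNAs miR-10a and miR-10b, too few for the list test, had -0.02 ± 0.32 and 1.116 ± 0.534.

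The second comparison asked the same of snoRNAs, tRNAs and other misc RNAs. The C/D box snoRNAs, guides of 2'-O-methylation of ribosomal RNA, were the one class that passed the set test with a preset correlation. Of 70 tested members 65 had a higher fitted level in cKO, with a median log2 difference of 0.21 (camera, adjusted p = 2.4e-09). With an estimated correlation the call ended (adjusted p = 0.32). The mean log2 level of the class differed by 0.19, against SDs of 0.15 and 0.13 (n = 6 each, exact two-sided permutation p = 0.043). It was above the Control mean in 6 of 6 cKO libraries; the difference was 0.24 in replicate numbers 1 to 3 and 0.14 in numbers 4 to 6.

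No single misc RNA passed an adjusted p of 0.05 of 1073 tested by edgeR or DESeq2 (0 each), and 77 had an unadjusted p under 0.05 in edgeR. No snoRNA of the C/D class passed over all misc RNAs, and 0 passed adjusted over the list alone. Its 4 members with the smallest p were Snord93, Snord91a, Snord92 and Snord1c, with log2 fold changes of 0.51 ± 0.18, 0.38 ± 0.17, 0.46 ± 0.21 and 0.32 ± 0.16 (SE). The most abundant misc RNAs, Snord43, Snord99, Gas5, Snord55 and Snord110, had 0.11 ± 0.21, 0.27 ± 0.15, 0.25 ± 0.31, 0.09 ± 0.16 and 0.15 ± 0.23. The smallest p values belonged to AI506816 (0.52 ± 0.16), a copy of tRNA-Cys (1.21 ± 0.38) and A230072E10Rik (-0.84 ± 0.28), each with an adjusted p of 0.61. Of the rest, a tRNA-Lys copy had 0.83 ± 0.31, 2 further tRNA-Cys copies 0.70 ± 0.26 and 0.64 ± 0.26, Rnu3a 0.60 ± 0.23, Gm16287 0.49 ± 0.19 and LOC100302626 -0.74 ± 0.29. The rise of those 2 further tRNA-Cys copies lay in cKO 1 to 3, at 8.57 to 11.3 and 8.82 to 14.5 CPM. In cKO 4 to 6 they had 4.26 to 5.65 and 5.06 to 6.49 CPM. Control libraries had 3.39 to 5.94 and 4.09 to 6.25 CPM. How reads that match several tRNA copies were counted is not stated. Near-identical copies may share reads, so which copy differs is uncertain. AI506816 and Snord93 followed nearly the same order over the libraries. Both were lowest in Control 4, at 84.8 and 65.4 CPM, and highest in cKO 1, at 160.4 and 140.5 CPM. Whether AI506816 and Snord93 share reads was not tested, so they may not be separate signals.

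The remaining misc RNA classes did not pass. The H/ACA box snoRNAs had a median of 0.04 over 11 members (adjusted p = 0.70), the Cajal body RNAs 0.16 over 6 (0.33), the small nuclear RNAs 0.12 over 16 (0.33), and the imprinted Snord115 and Snord116 group 0.08 over 4 (0.53). Classes were set by name, so the small nuclear class includes Rnu3a, a U3 RNA, although U3 RNAs are C/D box snoRNAs.

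The third comparison used the table of all RNAs, where reads on messenger RNAs are fragments. None of the 1474 tested transcript rows outside the miRNA and misc RNA classes passed in edgeR, with 67 at an unadjusted p under 0.05. DESeq2 called 9. Each value here is for a single transcript row. Degs2, Rnft2, Inpp5d, Tiam1 and Lrrc49 have other rows, so their values are not those of the whole gene. The smallest edgeR p values belonged to Shb, an adaptor protein gene (log2 fold change 1.71 ± 0.38), Pdzd2 (2.08 ± 0.48) and the sphingolipid desaturase Degs2 (-3.33 ± 0.77), each with an adjusted p of 0.54. DESeq2 called all 3, with adjusted p values of 0.0013, 0.0043 and 0.0026. It also called Mks1, Dnah17, Bsn, Rasgrp1, Rnft2 and Lrrc49, the last outside the naming rule and chosen after its value was seen. In edgeR the log2 fold changes of Mks1, Dnah17, the presynaptic scaffold Bsn, Rasgrp1 and Rnft2 were 4.61 ± 1.19, 1.67 ± 0.46, 2.69 ± 0.78, 3.81 ± 1.17 and 3.43 ± 1.06. Inpp5d and Tiam1 had 2.48 ± 0.77 and -1.17 ± 0.37. Several of these rest on few libraries: Rasgrp1 was above the Control mean in 2 of 6 cKO libraries, and its cKO level was 123 ± 181.7 CPM.

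The most abundant rows were the ribosomal RNAs Rn28s1 and Rn5s, the imprinted retrotransposon-like gene Rtl1, Mir127 and Mir27b. Their log2 fold changes were -0.07 ± 0.26, -0.08 ± 0.31, -0.85 ± 0.66, 1.74 ± 1.34 and -0.05 ± 0.21. Rtl1 and Mir127 overlap on opposite strands, and which of them held most reads differed between libraries. Mir127 held more than Rtl1 in Control e and in cKO a, b, d and e. Rtl1 held more in all other libraries, so this swing enters the log2 fold changes of Rtl1 and Mir127. The sum of both was 158302 ± 13893 CPM in Control and 153385 ± 26397 CPM in cKO (SD, n = 6 each, exact permutation p = 0.73).

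Gene lists in this table did not pass. The excitatory neuron genes had a median log2 difference of 0.17 over 7 tested rows (adjusted p = 0.75), the astrocyte genes 0.06 over 6 (0.92), the snoRNA host genes 0.01 over 6 (0.92) and the SAGA and ATAC subunits 0.00 over 5 (0.92). Other lists had fewer than 3 tested rows. Of other cell types, Dsp (dentate gyrus) had a log2 fold change of -0.15 ± 0.45, Slc1a2 (astrocytes) 0.44 ± 0.44 and Aqp1 (choroid plexus) 0.72 ± 1.003. Mean counts per library in Control and cKO were 8.33 and 11.8 for Reln, 7.50 and 7.33 for Gad2, 6.17 and 13.5 for Mbp, 2 and 3.67 for Cx3cr1, 2 and 2.33 for Csf1r. They were 8.17 and 4.67 for Flt1, 7.67 and 7.17 for Cldn5, 5.17 and 10.8 for Kl, 3.83 and 6.17 for Hba-a2 and 2.33 and 4.33 for Hba-a1. Slc1a2 and Mbp have several transcript rows, and the values given are for a single row of each. Grik4 had 23.8 and 126.7, with a range of 2 to 335 within cKO, and Gja1 had 483 and 3.83, with a range of 1 to 1666 within Control.

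The last comparison asked whether the make-up of the libraries differed. In the table of all RNAs miRNA rows held 45.0 ± 9.34% of counts in Control and 49.7 ± 9.61% in cKO, misc RNA rows 1.57 ± 0.08% and 1.59 ± 0.19%, and the rest 53.5 ± 9.33% and 48.7 ± 9.62% (SD, n = 6 each). Mir127 was counted with the miRNA rows and Rtl1 with the rest, so the swing of reads between them enters these shares. In libraries where Mir127 held more reads than Rtl1 the miRNA share was 44.6% to 61.3%. In the other libraries it was 34.5% to 47.1%. In the misc RNA table tRNAs held 41.8 ± 7.87% and 44.8 ± 7.66%, the class that holds the snoRNAs 32.0 ± 2.42% and 32.4 ± 2.06%, and other misc RNAs 26.2 ± 7.38% and 22.7 ± 6.69%. None of the 6 differences in share passed (exact two-sided permutation tests, unadjusted p values of 0.41 to 0.80, adjusted p values of 0.76 to 0.80).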

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

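The tests within and between the sets of replicate numbers, of neuronal RNA, of shared reads and of balanced splits were chosen after their results were seen, and the bound for neuronal RNA was changed after its value was known; the GC, depth and other split tests were chosen before. Among the groups of 6 values checked, 10 had a library far from the others, against 7.60 that chance would give at 1 in 20. The gap of the outermost library over the range of its group was 0.69 for miR-199a-5p in cKO (cKO 6 highest), 0.65 for miR-181a in cKO (cKO 4 highest), 0.63 for Rnu3a in Control (Control 5 lowest) and 0.67 for Snord110 in Control (Control 2 highest). It was 0.73 for Inpp5d in cKO, 0.91 for Aqp1 in cKO, where 1 library had 532 CPM and the next 57.4, and 0.74 for Kat2a in Control. The share of the snoRNA-holding class in cKO had a gap of 0.65, with cKO 5 lowest at 28.4%.

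In 1 Control library Mir127 had 128056 CPM and the next highest 3634 (gap 0.98), while Rtl1 was lowest there at 28614 CPM (gap 0.72). Across the 12 libraries one or the other of the pair held most reads. The coefficient of variation of the sum was 0.13, against 0.68 for Rtl1 and 1.19 for Mir127. A steady sum was already visible in the pattern, so it cannot tell reads shared by the overlapping transcripts from another exchange between them. In the miRNA table, counted apart, miR-127 had 103023 to 189169 CPM over the 12 libraries. The Mir127 row ran from 1412 to 139503 CPM. For these libraries the values argue against an exchange in which the miRNA itself swings as that row does. No other biological explanation was tested.

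The first component of miRNA levels held 46.6% of the variance. It set all libraries with replicate numbers 4 to 6 apart from those with numbers 1 to 3, in both groups. Within numbers 1 to 3, Control 1, Control 2, cKO 1 and cKO 3 lay at 8.30 to 9.02. Control 3 and cKO 2 lay at -0.98 and -0.41, nearer to numbers 4 to 6 (-6.78 to -4.01). Between these sets 220 miRNAs passed an adjusted p of 0.05 (edgeR). Library depth is argued against, since after thinning to the smallest total a gap of 3.09 remained (3.04 before). Hairpin GC content may play a part: its Spearman correlation with the loadings was -0.37, across miRNAs, which are not independent replicates. The labels give no batch, so a batch that follows these sets was not tested and stays open. Of 14 miRNA lists tested between the sets, those of cell types included, none passed camera (smallest adjusted p = 0.098, miR-29). Still, miR-204* and miR-486 were higher in numbers 1 to 3 by log2 values of 1.49 and 1.03, so a difference in cell make-up also stays open.

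The fall of the Dlk1-Dio3 miRNAs in cKO was weighed against 3 explanations and chance. Each set of replicate numbers holds 3 libraries of each group, and within the sets alone the median was -0.14 and -0.15; after a correction for hairpin GC it was -0.13, and in each case the list passed camera. Of 100 splits of the 12 libraries, 1, the real one, gave a camera p as small for this list (2.3e-07, next 4.0e-05), although in another split a different list reached 2.5e-07. A lower share of neuronal RNA cannot be told apart. The neuron-enriched miRNAs differed by -0.02, with 16 members lower and 6 higher. The gap between the locus and that list did not pass (-0.10, lower in 5 of 6 cKO libraries, exact permutation p = 0.14). An effect of Kat2a loss on the locus therefore stays a hypothesis beside that explanation.

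Over all 100 splits chance could not be excluded for the counts of miRNAs, miRNA lists and misc RNA classes. As many miRNAs as the real 1 were called in 5 splits, with up to 109 in another split, 39 splits called as many miRNA lists (real 1, highest other 4), and 56 as many misc RNA classes (real 1, highest other 5). For miRNAs the other 4 splits put 4 or 5 of the 6 libraries numbered 1 to 3 in one group. Of the 38 splits balanced over the sets, as the real one is, 1, the real one, called a miRNA. With the sets as a covariate miR-203 kept its call (adjusted p = 0.022), while the replicate number as a block ended it. Balanced splits reached the real count of lists in 18 cases and of misc RNA classes in 24. A real count of 0 is reached by all 100 splits whatever the data. For misc RNAs (highest other 226), transcript rows of the table of all RNAs (2) and gene lists (1) the splits say nothing about chance. The splits with 109 and 226 calls put 5 of the 6 libraries numbered 1 to 3 in one group. Among them were Control 1, Control 2, cKO 1 and cKO 3. Other splits with 5 of the 6 in one group called 0 miRNAs and 0 misc RNAs. Splits with the named libraries together and fewer of numbers 1 to 3 also called 0. The calls thus depend on which libraries are grouped, not on the number alone.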

How the results depend on the processing

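The fall of the Dlk1-Dio3 miRNAs kept its direction and call in all 9 other settings (medians -0.16 to -0.12, adjusted p 4.6e-07 to 0.00094) and without each of the 12 libraries (-0.15 to -0.12); the block and the covariate are balanced over the groups and cannot move a median. The C/D box snoRNAs stayed higher in 10 settings (0.16 to 0.38) and without each library (0.14 to 0.30), and their median of 0.21 lost its call with an estimated correlation and with fry (0 classes each). The count of 1 miRNA became 2 in DESeq2 and 0 with the total of the miRNA and misc RNA tables, in numbers 1 to 3 alone, in numbers 4 to 6 alone and without any 1 library (0 to 0); fewer libraries lower the power, and the cause was not tested for the total. The count of 1 miRNA list became 2 in numbers 4 to 6 alone (miR-29 lower) and was 1 to 2 without 1 library. The count of 0 transcript rows in the table of all RNAs became 9 in DESeq2 and 0 to 2 without 1 library. These were rows of Fbxw4 and Phka2, named after their values were seen. The cause was not tested. Counts of misc RNAs stayed at 0, and those of misc RNA classes at 1, without each library. No share of counts passed in any setting. The Kat2a difference of -1.28 CPM was -1.72 to -0.32 without 1 library. Of the named features, 66 values over the settings changed sign, none of miR-203; miR-203 lost its call in 16 settings, and 9 values gained one, all in DESeq2.

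Same-numbered libraries did not deviate together in every pair (correlations in the miRNA table of 0.41, -0.15, 0.13, 0.67, 0.24 and 0.27). The labels state no pairing, and these correlations neither show nor exclude a pairing by number. With the replicate block the count of 1 miRNA became 0 (miR-203 log2 fold change 0.73, adjusted p = 0.27), miRNA lists stayed at 1, misc RNAs at 0 and misc RNA classes at 1; in a sign-flip by number 0 shares passed. No paired analysis was run for the table of all RNAs because its columns carry no sample number in their names. For that reason its total was not used to scale the other tables.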

Other observations

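All tests here were chosen after the data were seen. Clusters of neighbouring miRNA genes were tested without regard to the fixed lists: miRNA genes on one strand with gaps of up to 50 kb, 31 clusters with 3 or more tested members. The large part of the Dlk1-Dio3 locus, with miR-411, miR-410, miR-541 and miR-381, fell in cKO (54 members, median log2 difference -0.11, camera adjusted p = 0.00016, and adjusted p = 0.0072 with an estimated correlation). Its other part, with miR-127 and miR-434, had a median of -0.12 over 19 members (adjusted p = 0.058). Another 3 clusters passed with the preset correlation, each at an adjusted p of 0.045. They were miR-23a, miR-27a and miR-24-2 (median 0.29, 4 members), miR-221 and miR-222 (-0.27, 4 members) and miR-298 and miR-296 (-0.37, 3 members). With an estimated correlation these 3 had adjusted p values of 0.29, 0.31 and 0.29.

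The miRNAs hosted by Htr2c, a serotonin receptor gene, had a median log2 fold change of -0.33 in cKO over 7 rows, from -0.42 for miR-448-5p to 0.00 for miR-448-3p, with miR-1298 (-0.33 ± 0.14), miR-1264-3p (-0.39 ± 0.17) and miR-764-3p (-0.40 ± 0.19) among them; none passed the edgeR test, with adjusted p values of 0.997. The group was picked after its values were seen, and the cluster test that holds 3 of the rows (miR-764-3p, miR-1264-3p and miR-1264-5p) did not pass, with an adjusted p = 0.071, and adjusted p = 0.39 with an estimated correlation. Carry-over of choroid plexus, which expresses Htr2c, is a candidate explanation. It would lower miR-204, which had a log2 fold change of 0.13 with a 95% interval of -0.48 to 0.75, so the test left this open.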
